A study of Mus musculus with 6 samples.

How the data were processed

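RNA was measured in the anterior cingulate cortex (ACC) of C57BL/6 mice by sequencing of polyadenylated transcripts. The labels name 6 libraries, 3 from mice given LPS (lipopolysaccharide, a bacterial endotoxin, 50 µg per kg) and 3 from mice given saline. Injections were intraperitoneal on postnatal day 14 and tissue was taken on postnatal day 45. Per the labels' protocols, RNA came from 1 mouse per library, after anaesthesia, cold perfusion, slicing and dissection by hand. The sex of the mice, the cage and litter, and the order or time of collection are not given in the sources used here. The library kit named in the labels is not stated to keep the strand, so reads from overlapping genes on opposite strands cannot be told apart.

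The authors deposited 1 table with raw read counts per gene and library, and FPKM values (length- and depth-scaled fragment counts) beside them. Per the submitters' processing notes, TopHat2 2.1, DESeq 1.10.1 and genome build GRCm38 were named. Their roles and order, the counting program and the annotation release are not given in the sources used here. The deposited counts were whole numbers in 14250 rows, of which 13562 carried an Ensembl identifier and 688 were named newGene and carried no position. Of the Ensembl identifiers, 13559 were found in GENCODE M21, which uses GRCm38, and positions were taken from it. The symbols of 23 rows had been turned into dates and were replaced by the reference symbol of their identifier. The smallest row total was 185 counts, and a low-count filter by the authors is not stated. Within a gene, the ratio of the authors' FPKM to their counts, set relative to Saline 1, departed from its library's median by over 10% in 9.82% of gene and library pairs. The reason was not tested.

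The counts were tested with edgeR 4.0.16 (quasi-likelihood test, robust option, TMM factors) in R 4.3.3, with treatment as the only term and all 6 libraries in the fit. The filter filterByExpr removed 0 of the 14250 rows. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Log2 changes are LPS relative to saline and each has a standard error (SE). CPM values, counts scaled to the library's size, were computed here with TMM factors.

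A set of 32 gene lists, fixed before the data were examined, covered cell types, synapses, inflammation, stress and activity genes. The 28 lists with at least 5 measured members, apart from the Y-linked label check, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2. Genes named in the text followed a rule fixed at the same time. It took up to 12 genes per direction with the smallest p among those past the threshold whose groups did not overlap. It skipped predicted genes, rows without a symbol, pseudogenes and mitochondrially encoded genes. It added a panel of 25 genes and the 2 members with the smallest p in each list. Further members of the lists, the genes near Ide and Btaf1, and the genes Hpcal4, Csrnp1, Nnt, Adamts1 and Ciart are named as well and were chosen after their values were seen. The panel genes C3, Il1b and Tnf were not analysed here, and the result of 1 short list is not reported here.

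Alternatives planned before the data were examined were the replicate number as a block, leaving out each library, RLE size factors, quantile normalization with limma, DESeq2 1.42.0, limma-voom with and without sample weights, no filter, a mean of at least 50 counts, a threshold of 0.1, a minimum of 1.5-fold, 1 surrogate variable (sva 3.50.0), camera with an estimated correlation, and fry. Alternatives added after seeing the data were limma on the authors' FPKM as log2(FPKM + 1) with a mean of at least 0.5, edgeR without the robust option, leaving out the newGene rows, and leaving out rows with over 4-fold range within a group.

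The steps were tested on simulated counts of 14250 genes drawn from the means and library sizes of these samples. The edgeR test recovered 169 of 350 genes changed 1.5-fold (48.29%), 283 of 350 changed 2-fold (80.86%) and 281 of 300 changed 3-fold (93.67%). It also called 78 of 70115 unchanged genes. Camera called the planted list of 27 genes in 5 of 5 runs. Counting all planted list genes as recovered, the 78 false calls were a larger share of all calls than the adjusted p threshold allows. The edgeR calls in the real data may therefore hold more false ones than that threshold states. The simulated genes were drawn independently of each other, so these runs do not test the preset correlation. No libraries were near-duplicates: the chi-square per degree of freedom between libraries was at least 32.1.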

Results

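Transcript counts in the anterior cingulate cortex, a frontal region tied to mood and pain, were compared between adolescent mice that had received LPS or saline as juveniles. The series concerns early inflammation, microglial engulfment of dendritic spines and later depression-like behaviour. Each group held 3 mice, each with 1 library. The saline libraries held 39308376, 39804999 and 37416194 counts and the LPS libraries 41270737, 41223469 and 36168687. Y-linked genes were detected in both groups and none was called different by edgeR. Eif2s3y had 23.1 ± 2.61 CPM in saline and 26.0 ± 4.09 CPM in LPS samples (SD, n = 3 each), and Kdm5d 25.0 ± 1.39 and 23.7 ± 2.61 CPM.

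At postnatal day 45, LPS mice had lower levels of part of the immediate early genes, the transcripts that neurons and other cells induce within minutes of stimulation. Of the 27 genes in the fixed list, 8 fell in LPS mice by edgeR over all genes tested and 0 rose. The kinase gene Sik1 went from 43.0 ± 5.23 CPM in saline to 17.5 ± 1.11 CPM in LPS samples (SD, n = 3 each), a fall of 1.30 on the log2 scale (SE 0.10, edgeR adjusted p = 0.00042). The nuclear receptor gene Nr4a1 fell by 1.04 (SE 0.107) and its relative Nr4a2 by 0.71 (SE 0.0947). Gadd45b, Klf4, Dusp5 and Dusp6 also fell, with log2 changes from -0.63 to -1.01. Dusp1, a phosphatase gene that switches off MAP kinases and overlaps the exons of another tested gene, went from 107 ± 8.10 to 29.4 ± 6.49 CPM (log2 -1.86, SE 0.171, edgeR adjusted p = 0.0192). Dusp1 lost its call without any one of LPS 1, Saline 1, Saline 2 or Saline 3 (edgeR adjusted p 0.0754 to 0.132). Dusp6 lost it without any one library other than Saline 3 (0.0977 to 0.189), Nr4a2 without LPS 3, Saline 1 or Saline 2 (0.0563 to 0.0802), and Nr4a1 without LPS 1 (0.0591).

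Adjusted over the list alone, 17 members fell and 1, Nptx2 (log2 0.24), rose. In 17 members every LPS sample lay below every saline sample, where chance gives 5% for this direction. Fos (log2 -1.16, SE 0.175), Arc (-1.74, SE 0.294), a synaptic activity gene, and Junb (-1.23, SE 0.204) were among them but missed the threshold over all genes, with edgeR adjusted p of 0.132, 0.293 and 0.217. DESeq2 called 17 members lower, these 3 included, and limma-voom 11. Without Saline 1, Saline 2 or LPS 1, edgeR called 5 members lower. Egr1 (-0.32, SE 0.231), Egr3 (-0.09, SE 0.134) and Bdnf (-0.03, SE 0.0726), a neuronal growth factor gene, did not pass in either tool. The median log2 change of the list was -0.77 and camera placed it below other genes with an adjusted p of 3.26e-22. That call is lost with an estimated correlation (camera, adjusted p = 0.625), and the adjusted p of the directional fry test was 0.0512. In 4 of the 9 other splits of the libraries camera also called this list, with a largest median of 0.44 in size. Each other split sets unequal numbers of LPS mice against each other, so it keeps part of any treatment difference. The heat shock list moved with the groups too, with library means of -0.13 to -0.11 in LPS and -0.02 to 0.03 in saline samples (fry adjusted p = 0.0298), but camera did not call it (adjusted p = 0.0839, or 0.625 with an estimated correlation). Most of this came from Hspa1a and Hspa1b, since the mean log2 change was -0.12 for all 16 members and -0.02 for the other 14. The share of counts in newGene rows also separated the groups, at 1.61% to 2.03% in LPS and 2.51% to 2.93% in saline libraries.

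**Figure D1:**
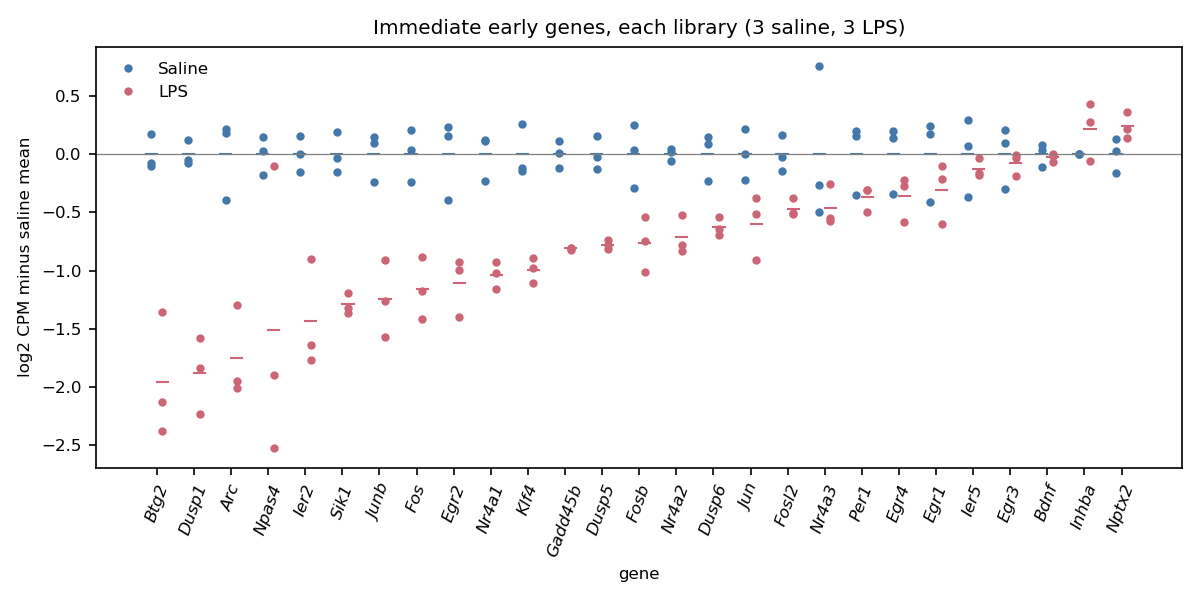
Log2 CPM of each of the 27 immediate early genes minus its saline mean, with 1 point per library and a short line at each group mean. The LPS points lie below all saline points for 17 genes, among them Dusp1, Arc and Sik1.

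Outside this list, 19 more genes fell. Cyr61, a secreted matrix protein gene, went from 36.4 ± 3.68 to 5.63 ± 1.1 CPM (log2 -2.69, SE 0.146, edgeR adjusted p = 8.44e-05). Apold1, an endothelial early response gene, fell by 2.25 on the log2 scale (SE 0.126) and Klf2, a flow-responsive transcription factor gene, by 1.11 (SE 0.0953). Hspa1b, an inducible heat shock protein gene, fell by 0.75 (SE 0.0855). Its near-identical neighbour Hspa1a had a log2 change of -0.81 (SE 0.142, edgeR adjusted p = 0.0751), and reads of this pair can be shared. In the endothelial list, 0 of 16 members passed in edgeR, DESeq2 or limma-voom, 1 had an unadjusted p under 0.05, and the median log2 change was 0.08.

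Other lower genes belonged to none of the fixed lists. Pheta1, which codes for an endosomal adaptor, had 8.31 ± 0.987 CPM in saline and 1.40 ± 0.136 CPM in LPS samples (log2 -2.57, SE 0.164, edgeR adjusted p = 9.93e-05). The zinc finger gene Zfp788 fell by 1.51 (SE 0.0953), the histone demethylase gene Kdm2a by 0.90 (SE 0.0566), Arl4d by 0.98 (SE 0.108) and Cntnap2, a neurexin family gene, by 0.77 (SE 0.0675). In the authors' FPKM, Kdm2a had a log2 change of -0.70 and a limma adjusted p of 0.0653.

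Higher genes were fewer. Wrb, which codes for a receptor that inserts tail-anchored proteins into the endoplasmic reticulum, rose from 9.99 ± 0.657 to 40.3 ± 4.07 CPM (SD, n = 3 each), a log2 change of 2.01 (SE 0.0979, edgeR adjusted p = 5.68e-05). Zfand2a, a stress-inducible zinc finger gene, rose by 1.34 (SE 0.0777), Hmga1, a chromatin protein gene, by 1.04 (SE 0.0772) and Hes5, a target of Notch signalling, by 0.91 (SE 0.0952). Hmga1 overlaps the exons of another tested gene, so its reads are uncertain. Csf2ra, a subunit gene of the GM-CSF receptor, rose by 0.86 (SE 0.0928), the imprinted gene Ndn by 0.74 (SE 0.0890) and Slc7a5, a large neutral amino acid transporter gene, by 0.48 (SE 0.0578). The call of Ndn was lost without Saline 3 (edgeR adjusted p = 0.0588), with the replicate number as a block (edgeR adjusted p = 0.112) and with FPKM (limma adjusted p = 0.0756). Dnah6, a dynein gene, rose from 0.527 to 2.78 CPM. Ide, the gene of insulin-degrading enzyme, rose from 50.5 ± 3.17 to 75.3 ± 2.94 CPM (log2 0.58, SE 0.0658, edgeR adjusted p = 0.00698). Btaf1, which lies 256 kb away on chromosome 19, rose by 0.54 (SE 0.0884, edgeR adjusted p = 0.0499). For Ide and Btaf1, a copy number or genotype difference between the groups of mice cannot be told apart from regulation here. The other 4 calls were newGene rows without a position.

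**Figure D2:**
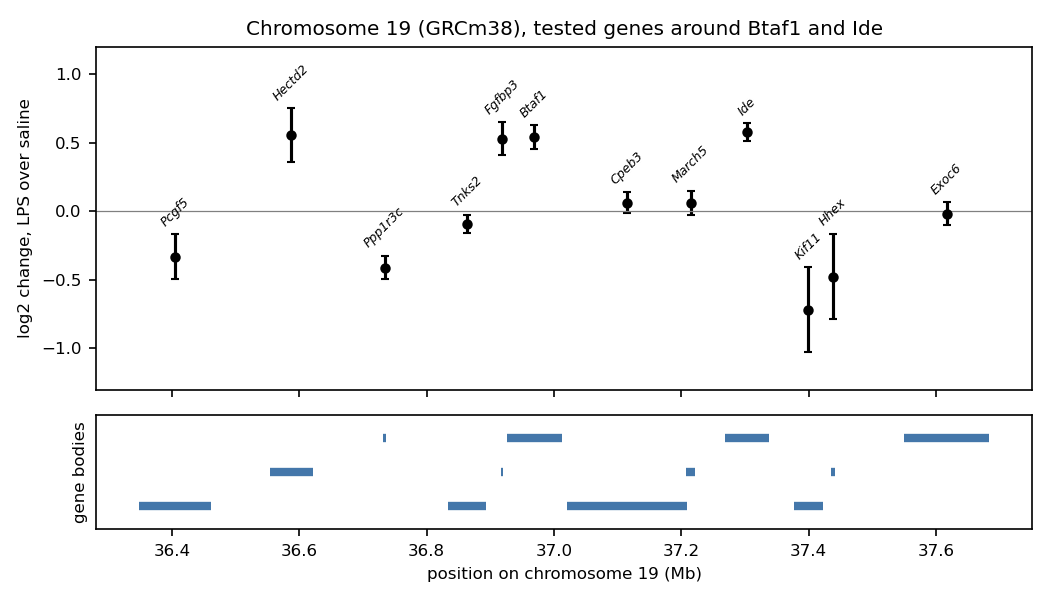
Log2 change (LPS over saline, bars are SE, 3 libraries per group) of tested genes on chromosome 19 against position in Mb, with gene bodies drawn below. Fgfbp3, Btaf1 and Ide lie between 0.53 and 0.58, and Cpeb3 and March5 between them lie at 0.06.

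In total, edgeR called 14 genes higher and 27 lower of the 14250 tested. In 1949 genes, 13.7% of those tested, the groups did not overlap, where chance gives 10%. At an unadjusted p under 0.05 there were 517 higher and 505 lower genes. DESeq2 called 60 higher and 80 lower, including all 41 of the edgeR calls. Btaf1 lost its call without any one of Saline 1, Saline 3, LPS 1, LPS 2 or LPS 3, with edgeR adjusted p from 0.0582 to 0.175.

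Genes of microglia, the brain's resident macrophages, did not pass as a group. In edgeR, DESeq2 and limma-voom, 0 of 24 members of the microglia list and 0 of 26 of the complement and phagocytosis list passed, with 2 and 1 at an unadjusted p under 0.05. Their median log2 changes were 0.03 and 0.02, with camera adjusted p of 0.892 and 0.775. Tmem119 had 25.5 ± 0.544 CPM in saline and 26.9 ± 1.47 CPM in LPS samples (SD, n = 3 each). Csf1r, the receptor gene on which microglia depend for survival, had 124 ± 9.43 and 128 ± 3.37 CPM. Csf1r overlaps the exons of another tested gene, so its reads are uncertain. Log2 changes were 0.01 for Trem2 (SE 0.145), 0.11 for Cd68 (SE 0.146), 0.09 for Itgam (SE 0.0804), 0.17 for Tlr4 (SE 0.281), -0.17 for C1qa (SE 0.0738) and -0.47 for Aif1 (SE 0.182). None of the 6 passed in edgeR. In Aif1 and C1qa each LPS sample lay below each saline sample.

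Cx3cr1, the microglial receptor of the neuronal chemokine fractalkine, varied too widely within the LPS group for a comparison. Its counts were 217, 421 and 413 in the saline libraries and 227, 1428 and 1319 in the LPS libraries, so 1 LPS library matched saline and the others were several times higher. The fitted level was 2.84-fold that of saline, with an SE of 0.829 on the log2 scale (edgeR adjusted p = 0.786). Without LPS 1 the log2 change was 1.98, with an edgeR adjusted p of 0.216. P2ry12, another microglial receptor gene, also varied within groups, at 19.9 to 49.0 CPM in saline and 26.5 to 50.8 CPM in LPS samples. P2ry12 overlaps the exons of another tested gene, so its reads are uncertain. Cx3cl1, the gene of fractalkine itself, had a log2 change of 0.04 (SE 0.264).

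**Figure D3:**
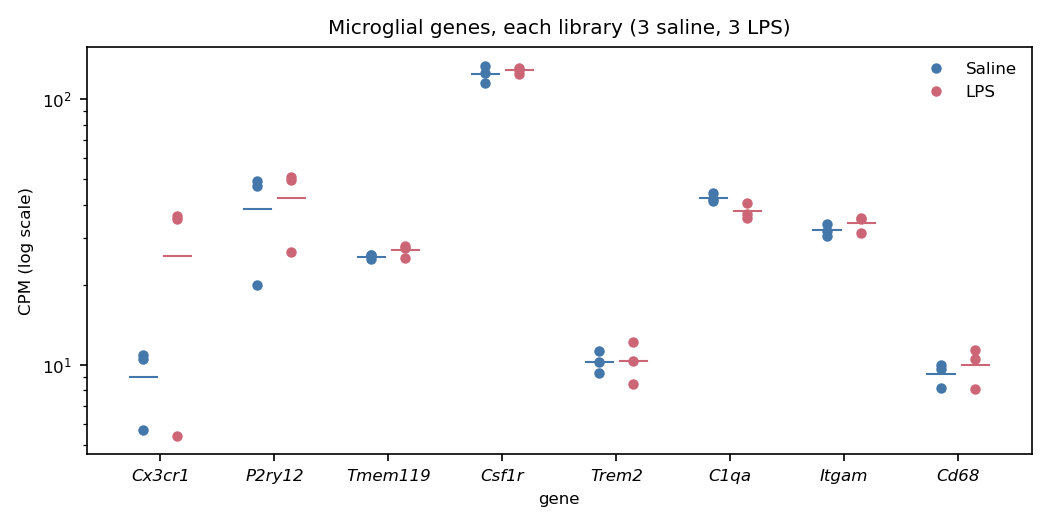
CPM on a log scale of 8 microglial genes, with 1 point per library and a line at each group mean. Cx3cr1 spans 5.41 to 36.1 CPM within the LPS group, whereas Csf1r and Tmem119 stay close together in both groups.

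No inflammatory list held a called gene. In edgeR, DESeq2 and limma-voom, 0 of 20 measured members passed in the cytokine and NF-kB list, 0 of 25 in the interferon list, 0 of 17 in the disease-associated microglia list and 0 of 14 in the microglia and neuron signalling list. Of the genes fixed for these lists, 20 of 31, 25 of 28, 17 of 22 and 14 of 16 were measured, so the rest are not covered. Those not covered in the cytokine list included Il1a, Il1b, Il6, Tnf, Ccl2 and Cxcl10. Its measured cytokine and chemokine genes were Il18 and Cxcl16, and the others were mainly receptor and signalling genes. Members at an unadjusted p under 0.05 numbered 2, 1, 0 and 3. Median log2 changes were -0.04, 0.04, 0.04 and 0.09, and camera called none of the 4 lists, with adjusted p from 0.0839 upward. The mean of the signalling list was 0.23, or 0.13 without Cx3cr1. Library means over all members were 0.10 to 0.34 in LPS and -0.06 to 0.06 in saline samples. Without Cx3cr1, LPS 3 was at 0.0419, level with Saline 1 at 0.0410 and Saline 3 at 0.0406. The mean of the interferon list was -0.01, opposite in sign to its median, and camera's direction for the microglia list, which it did not call, was lower although its median and mean were above 0. Il1r1, an interleukin-1 receptor gene, had a log2 change of 0.65 (SE 0.166) and Ptgs2, the inducible cyclooxygenase gene, -0.40 (SE 0.107), with edgeR adjusted p of 0.320 and 0.357. Adjusted over the list alone, both passed (edgeR, adjusted p = 0.0424 each).

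The synaptic and excitatory neuron lists held no called member by edgeR, DESeq2 or limma-voom, and camera called none of them. They covered 32 postsynaptic, 28 presynaptic, 24 spine actin and 15 GABA receptor genes and 20 excitatory neuron markers, with 1, 1, 0, 1 and 0 members at an unadjusted p under 0.05. Median log2 changes ran from -0.03 for GABA receptors to 0.03 for spine actin genes, whose mean was -0.03. Slc17a7, the vesicular glutamate transporter gene, had 1616 ± 91.9 CPM in saline and 1686 ± 43.8 CPM in LPS samples (SD, n = 3 each). Log2 changes were 0.11 for Dlg4 (SE 0.0562), a scaffold gene of the postsynaptic density, 0.07 for Gria1 (SE 0.0729) and 0.02 for Grin1 (SE 0.0663).

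Camera placed the inhibitory neuron list higher as a set, by a small amount. The camera adjusted p was 1.37e-03 for the 21 members, with a median log2 change of 0.13. This call is lost with an estimated correlation (camera, adjusted p = 0.625) and in fry (adjusted p = 0.298). Library means were 0.121 to 0.123 in LPS samples and -0.052, -0.053 and 0.105 in Saline 1, Saline 2 and Saline 3. Saline 3 thus lay close to the LPS samples. Markers of the striatum, which is rich in GABA neurons, had a median of 0.19, with library means of 0.06 to 0.18 in LPS and -0.06 to 0.08 in saline samples. Of the 10 splits of the libraries, 9, the real one included, called at least 2 lists by camera. No single member passed in edgeR, DESeq2 or limma-voom, and 5 had an unadjusted p under 0.05. Dlx1 (0.33, SE 0.0819), Gad2 (0.27, SE 0.0788), which codes for a GABA-synthesizing enzyme, and Lhx6 (0.25, SE 0.0780) had the largest values among the 7 members higher in every LPS sample. Gad1 (0.12, SE 0.0698), Sst (0.07, SE 0.0795) and Pvalb (-0.03, SE 0.172) did not pass. The adjacent neuropeptide list had a median of 0.10 and 0 called genes by the same tools, with 1 at an unadjusted p under 0.05.

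Members of the glucocorticoid and stress response list had log2 changes in both directions, 11 positive and 8 negative. Besides induced genes, the list holds the receptor genes Nr3c1 and Nr3c2 and the hormone gene Crh. None of 19 passed edgeR over all genes, while 6 rose and 3 fell adjusted over the list alone, 11 had an unadjusted p under 0.05, and DESeq2 called 3 higher and 2 lower and limma-voom 0. Fkbp5, a co-chaperone gene of the glucocorticoid receptor, had 15.9 ± 2.51 CPM in saline and 25.7 ± 1.55 CPM in LPS samples (log2 0.70, SE 0.117, edgeR adjusted p = 0.0568). Its edgeR adjusted p was 0.0190 without Saline 2, but 0.128 to 0.186 without any other single library. Hif3a (0.95, SE 0.184) and Cdkn1a (0.52, SE 0.108) were higher in every LPS sample, and Sgk1 (-0.29, SE 0.0627) and Ddit4 (-0.43, SE 0.104) lower in every one.

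Among other lists, edgeR called Hspa1b of 16 heat shock genes and no member of the rest. Median log2 changes were -0.08 for the heat shock list, -0.01 for astrocytes, 0.09 for reactive astrocytes, -0.07 for oligodendrocytes, 0.12 for their precursors, 0.06 for mural cells, 0.05 for monoamine receptors, 0.00 for perineuronal nets and 0.08 for mitochondrially encoded genes. Markers of neighbouring tissue had medians of 0.32 for meninges, 0.19 for striatum and -0.05 for thalamus. Camera called none of these 12 lists, with adjusted p from 0.0799 upward. Apart from heat shock genes, 22 members of the 11 lists had an unadjusted p under 0.05, and limma-voom called none. Gfap, an astrocyte filament gene, had a log2 change of 0.15 (SE 0.179). DESeq2 called 1 gene each in the astrocyte (Ppp1r3c), reactive astrocyte (Osmr), monoamine (Adrb1), perineuronal net (Tnc) and mitochondrial (mt-Nd3) lists. Of the lists with under 5 measured genes, choroid plexus (3 genes, median 0.04) and peripheral leukocytes (3 genes, median 0.68, with Lyve1 at 0.99 and library means of -0.87 in Saline 1 against 0.44 and 0.43 in the other saline libraries) had 0 called members in edgeR.

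**Figure D4:**
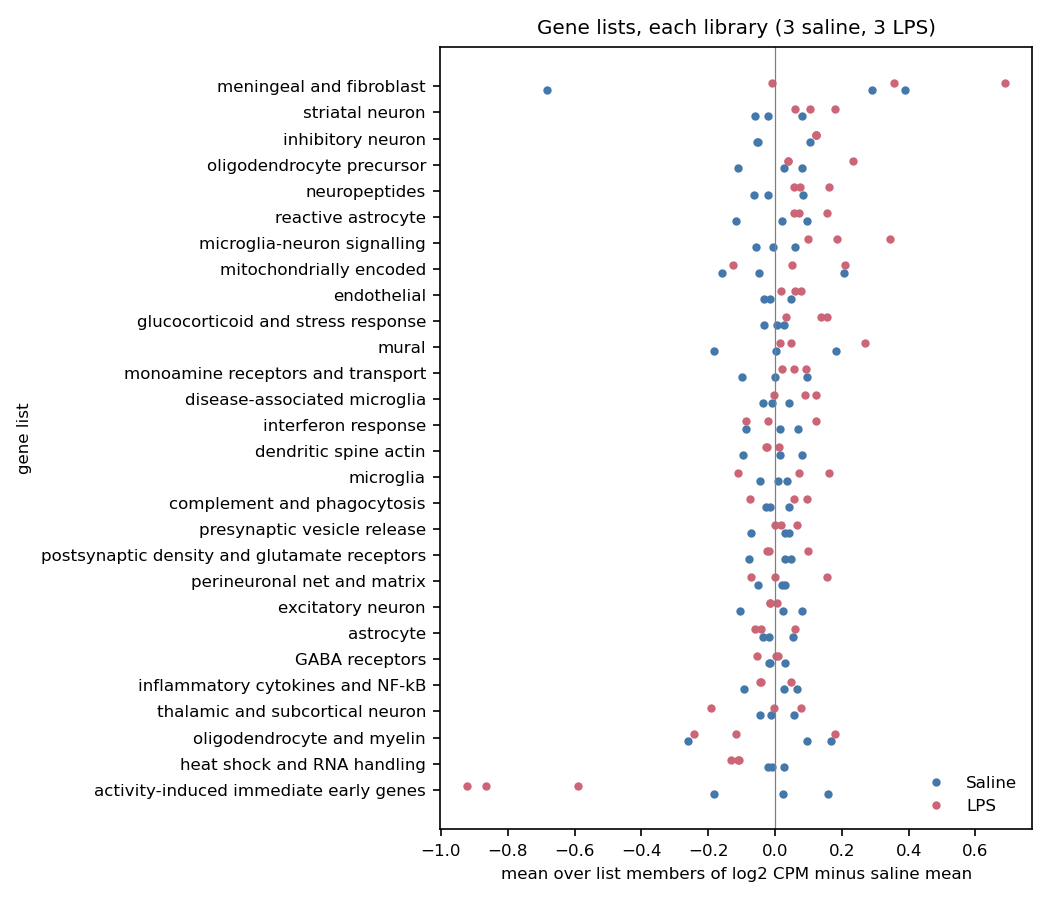
Mean over the members of each of 28 gene lists of log2 CPM minus the saline mean, with 1 point per library. The immediate early gene list separates the groups, at -0.92 to -0.59 in LPS libraries, and the meningeal list spreads widely within both groups.

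With 3 mice per group, the simulated recovery of 1.5-fold changes was 48.29%, so smaller differences in microglial or synaptic genes could be missed. Differences in handling, litter or time of collection between the groups are not recorded in the labels.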

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

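RLE size factors, no filter (which removes no row and so tests nothing), the surrogate variable, the non-robust fit and leaving out the newGene or wide-range rows kept each count within 1.5 times. Genes higher and lower were 60 and 80 with DESeq2, and genes higher were 23 at a threshold of 0.1, 9 at 1.5-fold or more and 8 with FPKM in limma, the last added after seeing the data. Immediate early genes lower were 17 with DESeq2. Lists higher were 4 with limma-voom, 2 with sample weights, 6 at a threshold of 0.1, 3 with FPKM, and 0 with an estimated correlation or fry. Lists lower were 2 with DESeq2 (cameraPR), 3 at a threshold of 0.1 and 0 with an estimated correlation. The adjusted p of the immediate early gene list was 0.625 with an estimated correlation and 0.0512 with fry, and that of the inhibitory neuron list 0.625 and 0.298. Fry called 1 list lower, the heat shock list (adjusted p 0.0298). Apart from stricter or looser thresholds, which change counts by construction, the cause was not tested. Leaving out 1 library gave 14 to 20 genes higher, 22 to 35 lower, 5 to 10 immediate early genes lower (5 without Saline 1, Saline 2 or LPS 1), 1 to 5 lists higher (5 without Saline 3) and 1 to 2 lists lower. Of the 41 called genes, 23 were called in all 6 such fits, and 4 (Ciart, Spty2d1 and 2 newGene rows) in none. Nr4a1 lost its call without LPS 1 (adjusted p 0.0591) and Ndn without Saline 3 (0.0588). Ndn also lost its call with the replicate number as a block (edgeR adjusted p 0.112) and with FPKM (limma adjusted p 0.0756). The alternative of a pseudocount of 0.1 applied only to normalized main values and was not run.

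With the replicate number as a block, 10 genes were higher and 21 lower, 7 immediate early genes were lower, 2 lists were higher and 1 lower. The numbers did not pair the samples: the correlations of deviations between same-numbered samples were -0.0266, 0.0252 and 0.0421.

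Of 2073 values of 99 named genes under these alternatives, 2006 kept direction and side of the threshold, 20 lost the call, 25 gained it and 22 changed sign, all of the last in 12 genes that passed in neither fit. The log2 change became -0.00034 for Trem2 with the block, -0.012 with limma-voom and -0.0058 with FPKM, 0.0076 for Pvalb with quantile normalization, and -0.019 for Cx3cl1 and -0.0023 for Itgam with FPKM. Leaving out 1 library gave ranges that cross 0 for Cx3cl1 (-0.23 to 0.20), Trem2 (-0.12 to 0.13), Bdnf (-0.085 to 0.0081), Kl (-0.016 to 0.37), P2ry12 (-0.18 to 0.38), Pvalb (-0.19 to 0.17), Sst (-0.0032 to 0.12), Csf1r (-0.018 to 0.091), Grin1 (-0.034 to 0.075), Tlr4 (-0.024 to 0.40) and Foxj1 (-0.20 to 0.12).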

Other observations

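Tests chosen only after the result was seen were those of neighbouring genes and of the genes between Ide and Btaf1, and the sum of the 2 Nnt rows. Lower genes outside the fixed lists included Ciart, a repressor of the circadian clock (log2 -0.65, SE 0.102, edgeR adjusted p = 0.0408), and Adamts1, a secreted protease gene (-1.33, SE 0.159, edgeR adjusted p = 0.0125). Ciart lost its call without any one library (edgeR adjusted p 0.0812 to 0.152) and Adamts1 without LPS 2, Saline 1 or Saline 2 (0.0563 to 0.0807). Meningeal genes were higher on the median by 0.32, but their library means ran from -0.68 to 0.39 in saline and from -0.01 to 0.69 in LPS samples, with Saline 1 lowest at -0.68.

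The lower immediate early genes were weighed against 3 technical explanations. A lower share of neurons is argued against by the excitatory neuron list, whose median log2 change was -0.00857 (SE 0.0234), where the explanation needs -0.39 or below. Removing the trend of log2 change with GC content and transcript length left the immediate early gene median at -0.80 (SE 0.159), against -0.77 before. Clock genes of opposite phase cannot decide on time of collection, because the bound lies within 2 SE. Their medians were -0.19 and -0.09. The difference of -0.11 (SE 0.102) lies below the 0.3 set beforehand by more than 1 SE but less than 2. Ciart was called lower. The other members of its phase, apart from Per2 (0.18, SE 0.113), also had negative log2 changes, such as Tef (-0.20, SE 0.0737). In the opposite phase, Nfil3 was at -0.30 (SE 0.107) and Arntl at 0.08 (SE 0.0633). Activity before perfusion may also have differed, through an effect of the treatment or through handling, and these data hold no test that separates those.

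With 10 splits of the 6 libraries, no share under 0.1 can be reached. The real split called 41 genes and the highest other split 12, and 1 split, the real one, reached 41. For gene lists, 9 of the 10 splits, the real one included, called at least as many lists as the 2 of the real split, and the highest other split called 10. The immediate early gene list was itself called in 4 of the 9 other splits, with an adjusted p down to 1.34e-08 (camera in limma) and a median of at most 0.44 in size against 0.77 in the real split. Each other split sets unequal numbers of LPS mice against each other, so part of any treatment difference remains in it. Calls in those splits therefore do not give a rate of false calls.

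Ide and Btaf1 were higher in each LPS library, and Fgfbp3 beside Btaf1 had a log2 change of 0.53 (SE 0.121), all near the 0.58 that 3 gene copies against 2 would give, while beyond Fgfbp3 Tnks2 was at -0.09, Ppp1r3c at -0.41 (SE 0.0856), Hectd2 at 0.56 (SE 0.197) and Pcgf5 at -0.33 (SE 0.165), and beyond Ide Kif11 was at -0.72 (SE 0.308), Hhex at -0.48 (SE 0.311) and Exoc6 at -0.02. A copy number or genotype difference between the groups may contribute. The median of Cpeb3 and March5, which lie between Btaf1 and Ide, was 0.0640 (largest SE 0.0865). That is below what a single duplicated segment spanning all these genes needs. Copies of separate segments that leave out Cpeb3 and March5 cannot be told apart from regulation here. Over the genome, 36 neighbouring gene pairs shared a direction at an unadjusted p under 0.05, where permuted positions gave 31.4 on average (permutation p = 0.230). Nnt, whose transcript is cut short in the J substrain, had a log2 change of 0.42 (SE 0.0825, edgeR unadjusted p = 0.000534). Its summed counts were 694, 645 and 639 in the saline and 967, 893 and 854 in the LPS libraries, so the groups did not overlap. The change lies below the 1 that a full J against N contrast would need. By 2 SE, it is not clearly below the bound of 0.5 set beforehand, so a substrain difference stays open.

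Cx3cr1 is one of 174 genes whose CPM differed over 4-fold between libraries of 1 group, 41 of them newGene rows without a position. The other 133 overlapped the exons of another tested gene in 42.1% of cases against 16.7% of other placed genes (odds ratio 3.63, 95% interval 2.52 to 5.21, Fisher's exact test), consistent with reads assigned to one model in some libraries and to another elsewhere. Cx3cr1 itself overlaps no exon of another tested gene, and Csrnp1, which lies inside its annotated span on chromosome 9 (119901616 to 120069879, GRCm38), had 492, 382 and 292 counts in LPS 1, 2 and 3, differences too small to supply the extra Cx3cr1 counts in LPS 2 and 3. Hpcal4, a neuronal calcium sensor gene, split the same libraries, at 253 to 292 CPM in the saline libraries and LPS 1 and at 1588 and 1540 CPM in LPS 2 and LPS 3. For Cx3cr1 the origin of the split stays open, a true difference among the LPS mice included.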
